A study of Mus musculus with 4 samples.

How the data were processed

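Gene expression was measured by RNA sequencing in primary cultures of mouse inner ear cells, grouped by the cell type label into vestibular cultures (2 samples) and cochlear cultures (2 samples). The vestibular part of the inner ear senses head movement and gravity, and the cochlea senses sound. Per the labels' protocols, total RNA was taken up in TRIzol and made into libraries with a TruSeq stranded kit that selects mRNA. The labels number the samples 1 and 2 within each group. Nothing in them says that the samples came from separate cultures or animals, so the p-values below measure only the spread between these samples.

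The deposited values are FPKM (fragments scaled by transcript length and library size), one value per gene symbol and sample, as the file headers give them. Per the submitters' processing notes, the tools were TopHat2 2.1.1, Bowtie2 2.2.8, SAMtools 0.1.18 and Cuffdiff 2.2.1 on the mm10 build. Their settings, the gene annotation, the strand setting and the scaling between samples are not given in the sources used here. FPKM divides by transcript length and by library size, so a value depends on the transcript model, and a very short gene reaches a high FPKM from few fragments. Each file held 24346 symbols in the same order, and no column lay outside the 4 samples.

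The ribosomal protein gene Rpl26 is listed at 0 in all 4 libraries, so an exact 0 may not mean that a gene was silent. A gene with an exact 0 is therefore described only as listed at 0, with each library's value. The FPKM totals were 519122 and 513162 in vestibular libraries 1 and 2, and 516227 and 479380 in cochlear libraries 1 and 2. The number of fragments per library is unknown, so no counting interval is given. Among short noncoding RNA genes, ratios of values between libraries clustered at whole-number ratios (tolerance 0.1 percent, ratios up to 4). These genes were chosen by the symbols of microRNA, small nucleolar and small Cajal body RNA genes, not by length. The most common ratios gave the FPKM that 1 fragment is worth in one library relative to another, and it ranged 1.16-fold over the 4 libraries. For the pair of cochlear libraries the most common ratio was 2.05, and the value used, 1.02, was taken through vestibular library 1. In that pair 14 of 28 short genes lay at this ratio or a whole-number multiple of it, against 24 of 34 between vestibular library 1 and cochlear library 2.

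Genes with a mean FPKM of at least 1 over the 4 samples were kept (13200 genes). Values were taken as log2(FPKM + 1), and a log2 difference is vestibular minus cochlear on that scale, which understates the difference of low genes. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, 2-sided), with Benjamini-Hochberg adjustment over the genes kept and a threshold of 0.05. With 2 samples against 2 the smallest 2-sided exact permutation p is 0.333, so no single gene can be called by permutation, and every call rests on the spread that limma shares across genes. The prior degrees of freedom were 1.71. The values are FPKM, so no count model was used.

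A total of 42 gene lists were fixed before the data were examined, covering cell types of the inner ear and its surroundings, matrix, patterning, signalling, metabolism and stress. The 39 lists with at least 5 members kept were tested with camera at a preset correlation of 0.01, which asks whether a list lies apart from the other genes, with adjustment over those 39 lists. Camera with an estimated correlation was run beside it. Fry was run as well: its directional p asks whether a list's genes move on balance one way, its mixed p whether they change in either direction, and neither compares a list with other genes. Members past the threshold were counted over all genes tested and adjusted over the list alone. The skeletal muscle, red blood cell and HOX lists had fewer than 5 members kept and are given as values.

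Named genes followed a rule set at the same time as the lists. Per direction it took the 12 genes with the largest log2 difference among those past the threshold, with groups that do not overlap, a mean FPKM of at least 5 in the higher group and no predicted or clone names. Places left open were filled by the smallest unadjusted p under the same conditions. It also took up to 4 members per list, those with the highest mean FPKM where fewer than 2 members passed, and the 5 genes with the highest mean FPKM in each group. Genes named outside this rule are said to have been chosen after their values were seen.

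Gene positions came from GENCODE release M21 on GRCm38, the assembly that mm10 names. Of the tested genes, 12733 (96.5%) matched one of its symbols, and transcript length and GC content were taken from the longest transcript, protein-coding where there was one. The fit was tested on simulated data for this comparison: 13200 genes, 20 simulations, 200 changed genes in each. Limma called 1.5% of genes changed by a log2 of 1, 45.8% at 2, 82.5% at 4 and 91.7% at 6, with 5 false calls per simulation on average. Camera called 20 of 20 lists moved by a log2 of 1 and 0 of 380 unmoved lists. The simulated genes varied independently, with a spread drawn from limma's own fitted prior and the same in both groups. These counts thus do not cover gene calls in data that depart from that model, or lists whose genes move together. In the real data the estimated correlation within the lists called by camera ran from 0.136 (interferon response) to 0.842 (ribosomal protein).

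Alternatives set then as well were pseudocounts of 0.1 and 5, no filter, a filter at a mean FPKM of 5, upper quartile scaling, quantile normalization, rescaling each sample to the same total (TPM), a replicate block, leaving out each sample in turn, other settings of eBayes, a log2 minimum of 1, one row per symbol, and the other list tests. Alternatives added after seeing the data were an adjusted p below 0.10 and leaving out short noncoding RNA genes (95 of the genes kept). Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.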

Results

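RNA sequencing profiles of primary cultures from the mouse inner ear were compared between 2 vestibular and 2 cochlear samples, to find the genes expressed differently by cells from these parts of the organ. The number of genes with an FPKM of at least 1 was 13094 and 12853 in vestibular libraries 1 and 2, and 12994 and 12644 in cochlear libraries 1 and 2. The highest mean values in the vestibular cultures belonged to the microRNA gene Mir130c (10766 and 10756 FPKM in vestibular libraries 1 and 2, against 1054 and 3091 in cochlear libraries 1 and 2), Apoe, Mgp, the microRNA gene Mir1892 and Lyz2. Mir1892 was listed at 10089 FPKM in vestibular library 2 and at 0 in the other 3 libraries. Mir130c and Mir1892 span 82 and 80 nt, so their values can come from few fragments. Mir1892 overlaps Sptssa on the same strand and Mir130c overlaps Kdelc2 on the other strand, and fragments may be shared with these genes. In the cochlear cultures the highest were Spp1, Mgp, Eef1a1, Tmsb4x and Clu. The matrix protein gene Mgp stood at 6631 ± 2160 FPKM in vestibular and 4691 ± 1329 in cochlear cultures (SD, n = 2 each), and the secreted phosphoprotein gene Spp1 at 3346 ± 1059 and 4918 ± 649.

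Libraries of a group were closer to each other than to the other group by the median absolute log2 difference, which was 0.218 between the vestibular and 0.171 between the cochlear libraries and ran from 0.226 to 0.332 between groups. Correlations separated the groups less. Across genes, Pearson's r of log2(FPKM + 1) was 0.911 between the vestibular libraries and 0.892 between the cochlear libraries. Between groups it was 0.910 for vestibular 1 with cochlear 1, 0.863 for vestibular 2 with cochlear 1, 0.838 for vestibular 1 with cochlear 2 and 0.802 for vestibular 2 with cochlear 2. These correlations run across genes, which are not independent replicates. The first principal component held 57.0% of the variance, with the vestibular libraries at 30.6 and 57.0 and the cochlear libraries at -16.7 and -70.8. The second held 25.9% and separated the libraries by number. Vestibular 1 and cochlear 1 stood at 23.8 and 40.5, and vestibular 2 and cochlear 2 at -36.0 and -28.3.

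Tmprss3, a transmembrane serine protease gene mutated in inherited deafness, stood at 91.9 ± 0.903 FPKM in cochlear and 1.22 ± 0.0916 in vestibular cultures (SD, n = 2 each). Prss36, which encodes a secreted serine protease, stood at 503 ± 76.2 FPKM in cochlear and 4.38 ± 0.0339 in vestibular cultures. Sdr16c5, a retinol dehydrogenase gene, stood at 34.9 ± 0.186 and 0.290 ± 0.158 FPKM. The small nucleolar RNA gene Snora44 was listed at 44.8 and 43.8 FPKM in the cochlear libraries and at 0 in both vestibular libraries. These 4 genes were lower in the vestibular cultures past the threshold of limma, with log2 differences of -5.39 (SE 0.11) for Tmprss3, -6.54 (SE 0.15) for Prss36 and -4.81 (SE 0.15) for Sdr16c5. Their adjusted p was 0.0153 for Tmprss3, Prss36 and Snora44, and 0.0414 for Sdr16c5. These differences are on the log2(FPKM + 1) scale, which understates the change of low genes. All 4 calls were lost on leaving out any library: without vestibular 1, vestibular 2, cochlear 1 and cochlear 2 the adjusted p was 0.0991, 0.229, 0.104 and 0.115 for Prss36, 0.0801, 0.229, 0.122 and 0.189 for Tmprss3, 0.0963, 0.229, 0.137 and 0.445 for Sdr16c5, and 0.0900, 0.229, 0.129 and 0.249 for Snora44. Tmprss3 lies on chromosome 17 at 31179265 to 31198977, Prss36 on chromosome 7 at 127932638 to 127946725, and Sdr16c5 on chromosome 4 at 3995936 to 4019663, all on the minus strand of mm10 and protein-coding. Snora44 lies on chromosome 4 at 132309941 to 132310069 on the plus strand, inside the noncoding host gene Snhg12 of the same strand, and its cochlear values may share fragments with that host.

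Limma called 0 genes as higher in vestibular cultures, and 4 of 13200 in all. At an unadjusted p under 0.05 there were 2398 genes, 1005 of them higher in vestibular and 1393 higher in cochlear cultures, where chance alone would give 660. The groups did not overlap in 7301 genes (55.3%, against 33.3% by chance). No gene passed when any single library was left out: the count was 0 without vestibular 1, without vestibular 2, without cochlear 1 and without cochlear 2, with 2724, 1762, 1908 and 1018 genes at an unadjusted p under 0.05. Lone samples in those fits were assumed to vary like the other group.

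Among the genes higher in cochlear cultures that did not pass (8 genes, limma adjusted p 0.0665 for each), the voltage-gated potassium channel gene Kcna2 stood at 28.7 and 34.8 FPKM in cochlear libraries 1 and 2, and at 1.03 and 0.488 in the vestibular libraries. Rab15, a GTPase gene of endosomal traffic, stood at 74.7 and 81.9 against 4.52 and 3.10 FPKM. The tetraspanin gene Tspan8 stood at 90.8 and 92.8 against 9.97 and 7.41, and Plet1 at 15.7 and 19.2 against 0.831 and 1.03. The carboxylesterase gene Ces1d stood at 32.0 and 34.5 against 3.40 and 3.86 FPKM, and Enho, which encodes the peptide adropin, at 58.1 and 69.9 against 9.07 and 8.07. The metal transporter gene Slc39a8 had 22.6 and 20.8 against 3.41 and 3.71 FPKM, and Pxdc1 had 83.1 and 88.2 against 18.3 and 17.3. Log2 differences of these genes ran from -4.23 to -2.21.

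Among genes higher in vestibular cultures, the 12 taken by the smallest p did not pass (limma adjusted p 0.0665 to 0.0902). Sparcl1, a SPARC-like matrix glycoprotein gene, stood at 491 and 713 FPKM in vestibular libraries 1 and 2 and at 99.5 and 98.5 in the cochlear libraries (log2 difference 2.57). Cdh11, a cadherin gene of mesenchymal cells, stood at 205 and 225 against 75.3 and 64.8. Fbln5, an elastic fibre gene, had a mean of 38.8 against 8.85 FPKM, and Antxr1, which encodes a collagen-binding receptor, 66.9 and 65.8 against 19.8 and 18.1. The adhesion molecule gene Vcam1 had a mean of 49.8 against 16.9 FPKM, and the transcription factor gene Tbx15 8.88 and 12.6 against 0.852 and 0.752. The hedgehog co-receptor gene Boc had 49.5 and 43.1 against 16.4 and 14.2 FPKM, and Cbr2 42.0 and 32.8 against 7.83 and 6.88. Hs6st2, St3gal2 and Smpd3 had log2 differences of 1.67, 1.43 and 2.07. The microRNA gene Mir678 was listed at 296 and 558 FPKM in the vestibular libraries and at 0 in both cochlear libraries. It lies on chromosome 10 at 76207326 to 76207409, inside Prmt2 on the same strand. Smpd3, Rab15 and Enho overlap a protein-coding gene of the other strand (Prmt7, Fntb and Dnaic1), and their values could be shared with it if strand was not used in counting.

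**Figure D1:**
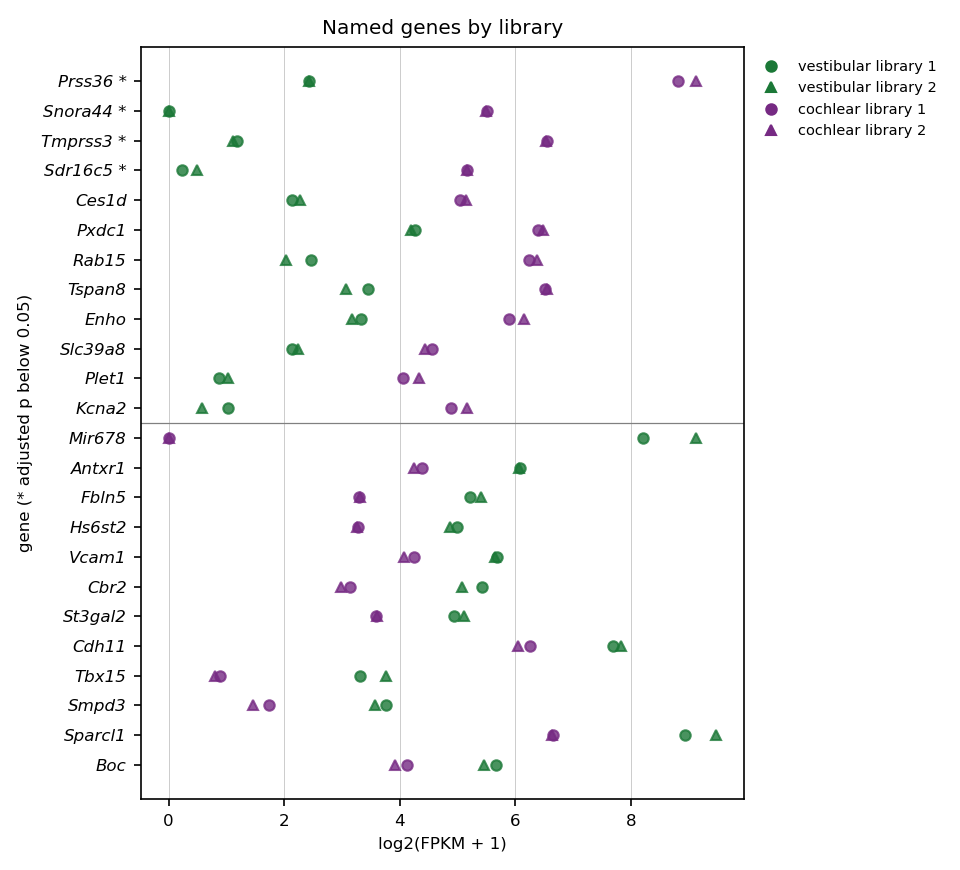
Expression of the 24 genes taken per direction, as log2(FPKM + 1) on the x axis, with one point per library (green vestibular, purple cochlear, circles library 1, triangles library 2) and genes higher in cochlear cultures above the line. Stars mark the 4 genes past an adjusted p of 0.05, and in each gene both libraries of one group lie beyond both of the other.

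Over the gene lists, camera placed 6 of 39 past the threshold, 3 higher in vestibular and 3 higher in cochlear cultures. None of these 6 held with an estimated correlation (adjusted p 0.912 for each). Of the 609 distinct listed genes tested, limma called 0 over all genes, 179 had an unadjusted p under 0.05 (86 higher in vestibular, 93 higher in cochlear), and 27 lists had at least 1 member past the threshold adjusted over the list alone.

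Epithelial marker genes were lower in vestibular cultures, in 18 of 18 members tested (median log2 difference -2.12, camera adjusted p 6.68e-06, and adjusted p 0.912 with an estimated correlation). The keratin gene Krt8 stood at 663 and 687 FPKM in cochlear libraries 1 and 2, 297 in vestibular library 1 and 10.5 in vestibular library 2. Krt18, its keratin partner, stood at 628, 719, 305 and 11.6 FPKM in the same order, and the claudin gene Cldn4 at 158, 226, 169 and 15.0. Cldn6 had 134 and 217 FPKM in the cochlear and 88.8 and 5.59 in the vestibular libraries. Of the 18, 2 passed adjusted over the list alone and 7 had an unadjusted p under 0.05. The median of the list was 4.93 and 2.57 on the log2 scale in vestibular libraries 1 and 2, and 5.18 and 5.98 in cochlear libraries 1 and 2. The list passed camera without any one library, and with vestibular 2 left out its adjusted p was 1.26e-05 and its median difference -1.04, against -3.14 without vestibular 1.

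Genes of fibroblasts and collagen matrix were higher in vestibular cultures, in 25 of 25 members (median log2 difference 1.18, camera adjusted p 4.56e-08, and adjusted p 0.912 with an estimated correlation). The matrix glycoprotein gene Sparc stood at 2235 and 5305 FPKM in vestibular libraries 1 and 2, and at 1132 and 1347 in the cochlear libraries. The type I collagen gene Col1a2 stood at 1140 and 3452 against 492 and 218 FPKM. Fibronectin (Fn1) and lysyl oxidase (Lox) genes overlapped between groups, with 1323 and 595 against 1017 and 521 FPKM, and 567 and 993 against 674 and 731. In this list 4 members passed adjusted over the list alone. Its median was 6.93 and 7.08 on the log2 scale in the vestibular and 6.05 and 5.78 in the cochlear libraries, so it lay opposite to the epithelial list. It passed camera without any one library (adjusted p up to 6.27e-06, without vestibular 1).

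Macrophage and leukocyte genes were higher in vestibular cultures in 16 of 17 members (median log2 difference 3.34, camera adjusted p 0.0499, and adjusted p 0.912 with an estimated correlation), and cochlear library 2 stood apart. The lysozyme gene Lyz2 stood at 5103 and 4245 FPKM in the vestibular libraries, 3902 in cochlear library 1 and 10.3 in cochlear library 2. The complement genes C1qa, C1qb and C1qc stood at 498, 548 and 535 FPKM in cochlear library 1, and at 0.516, 0.528 and 0.853 in cochlear library 2. In vestibular libraries 1 and 2 they had 629 and 419 FPKM (C1qa), 633 and 435 (C1qb), and 720 and 460 (C1qc). The median of the list was 7.56, 7.16 and 6.88 on the log2 scale in vestibular 1, vestibular 2 and cochlear 1, and 0.60 in cochlear 2. Without cochlear 2 the median difference was 0.05 and the list did not pass (adjusted p 0.629). It also did not pass without vestibular 1 (0.253) or without vestibular 2 (0.111). No member passed adjusted over the list alone, and 0 of 17 had an unadjusted p under 0.05 in limma.

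**Figure D2:**
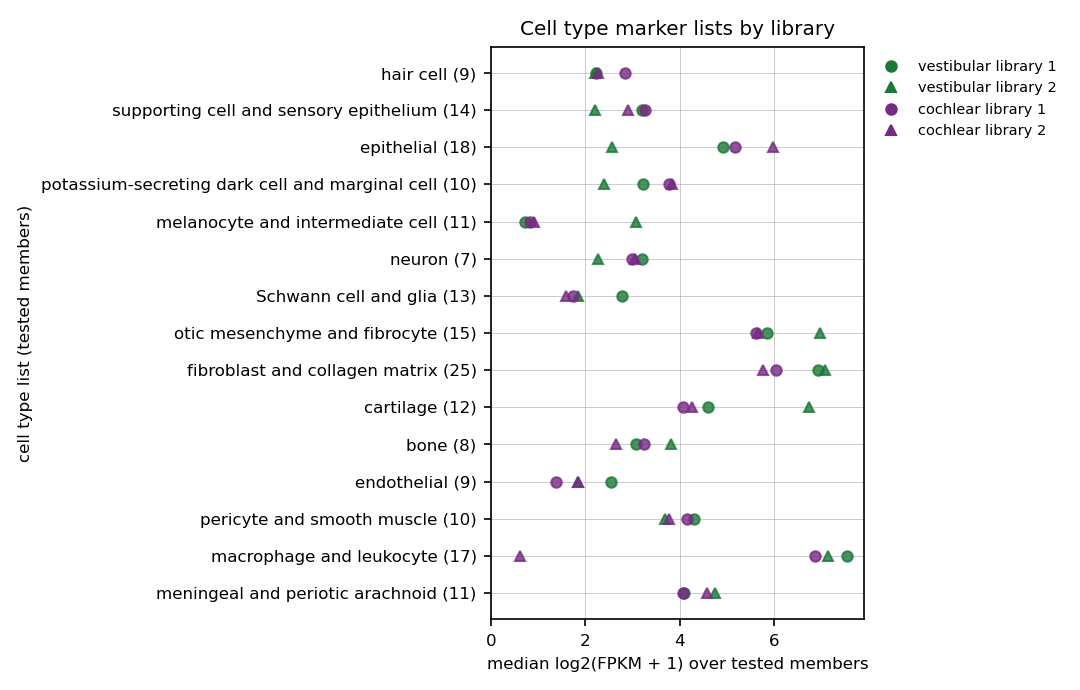
Median log2(FPKM + 1) over the tested members of 15 cell type lists, one point per library (green vestibular, purple cochlear, circles library 1, triangles library 2), with the number of tested members beside each name. The macrophage list stands at 0.60 in cochlear library 2 and at 6.88 or more in the other 3 libraries, and the epithelial list is lowest in vestibular library 2 (2.57).

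Other mesenchymal lists did not pass camera. Cartilage genes were higher in vestibular cultures in 9 of 12 members (median log2 difference 1.99, adjusted p 0.0768), and vestibular library 2 stood apart. The type II collagen gene Col2a1 had 543 and 2365 FPKM in vestibular libraries 1 and 2, and 83.9 and 38.5 in the cochlear libraries. Col9a1 had 74.8, 621, 36.4 and 48.7 FPKM in vestibular 1, vestibular 2, cochlear 1 and cochlear 2, Col11a1 96.6, 546, 49.5 and 81.6, and Col9a3 33.7, 663, 21.6 and 21.9. The median of the cartilage list was 6.76 on the log2 scale in vestibular 2, and 4.61, 4.08 and 4.26 in vestibular 1, cochlear 1 and cochlear 2. Much of its difference thus came from vestibular 2, and 1 member passed adjusted over the list alone. Bone genes were higher in 6 of 8 (median 1.16, adjusted p 0.0851; 0.0235 without vestibular 2), with the dentin matrix gene Dmp1 at 171 and 80.6 against 15.0 and 15.0 FPKM, and Alpl at 4.20 and 3.05 against 11.4 and 91.7. Otic mesenchyme and fibrocyte genes were higher in 10 of 15 (median 0.91, adjusted p 0.578). Their list median was 6.99 on the log2 scale in vestibular 2, and 5.85, 5.62 and 5.66 in vestibular 1, cochlear 1 and cochlear 2. In vestibular 1 they lay on both sides of the cochlear libraries (Gjb2 at 19.9 against 77.7 and 74.5 FPKM, Otor at 109 against 71.1 and 101). The direction thus leaned on vestibular 2. Their members went both ways: Car3 had 500 and 1569 against 234 and 148 FPKM, while the retinoic acid synthesis gene Aldh1a2 had 69.8 and 64.3 against 298 and 399, and Tgfbi 95.3 and 126 against 343 and 476. Coch, the cochlin gene of fibrocytes, had 797 FPKM in vestibular 2 and 56.5, 127 and 100 in vestibular 1, cochlear 1 and cochlear 2. Adjusted over the list alone, 1 bone gene and 2 genes of the otic mesenchyme list passed.

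Meningeal and periotic arachnoid genes were higher in vestibular cultures in 9 of 11 members (median 1.28, camera adjusted p 0.0980). The prostaglandin synthase gene Ptgds had 443 and 3402 against 94.2 and 140 FPKM. The median of this list was 4.09 and 4.76 on the log2 scale in vestibular 1 and vestibular 2, and 4.08 and 4.58 in cochlear 1 and cochlear 2. These medians lie close together and do not place the difference in a single library. Both vestibular libraries lay above both cochlear libraries in 7 of the 11 members, and below them in 2. Over all genes tested, the groups did not overlap in 55.3%. Pericyte and smooth muscle genes were higher in 7 of 10 (median 0.48, adjusted p 0.283), with Tagln at 149 and 192 against 74.3 and 70.3 FPKM and Acta2 at 72.1 and 165 against 34.4 and 23.3. Proteases of matrix remodelling were higher in 13 of 20 (median 0.62, adjusted p 0.0980), and this list passed without vestibular 2 (adjusted p 0.00659) and without cochlear 1 (0.0435). The gelatinase gene Mmp2 had 476 and 461 FPKM against 201 and 204, and the inhibitor gene Timp3 375 and 964 against 279 and 277. Basement membrane genes were higher in 11 of 20 (median 0.15, adjusted p 0.848), with Col4a1 at 132 and 356 against 124 and 133 FPKM. Endothelial genes were higher in 6 of 9 (median 0.17, adjusted p 0.827), although Emcn, the endomucin gene, had 14.5 and 34.3 FPKM in the vestibular and 112 and 287 in the cochlear libraries. Endothelial genes not kept include Pecam1 and Tie1, at most 0.155 and 0.0769 FPKM in any library, and Cldn5, listed at 0 in all. Adjusted over the list alone, 3, 4, 2, 3 and 0 members passed in the meningeal, pericyte, protease, basement membrane and endothelial lists.

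Of 28 hair cell genes 27 were in the files and 9 were kept, 6 of them higher in cochlear cultures (median log2 difference -0.25, camera adjusted p 0.342), and 3 passed adjusted over the list alone. Cib2, a gene of hair cell mechanotransduction, stood at a mean of 20.5 FPKM in vestibular and 19.7 in cochlear cultures. Espn, an actin-bundling gene, had 4.59 and 4.53 against 7.95 and 17.2. Supporting cell and sensory epithelium genes were split evenly, 7 of 14 each way (median 0.09, mean -0.35, camera placing the list lower, adjusted p 0.874). Otoa, which encodes a protein that anchors gel to the sensory epithelium, had 9.40 and 3.61 FPKM in the vestibular and 29.0 and 129 in the cochlear libraries. Genes of potassium-secreting dark and marginal cells were split 5 of 10 (median -0.12, adjusted p 0.578, 1 passed adjusted over the list alone), with the sodium pump gene Atp1b1 at 389 and 110 against 590 and 792 FPKM. Otoconia and endolymph genes were higher in cochlear cultures in 6 of 10 (median -0.29, camera adjusted p 0.585). This was the only list past fry's directional test (adjusted p 0.0245), and 2 of its members passed adjusted over the list alone. The carbonic anhydrase gene Car2 had 21.6 and 27.7 against 51.0 and 94.5 FPKM, while Sparcl1, in this list too, went the other way.

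Neuron genes were higher in vestibular cultures in 4 of 7 members (median 0.56, camera adjusted p 0.531, 1 passed adjusted over the list alone). Map2 went the other way, at 8.48 and 1.79 against 11.9 and 22.9 FPKM. Schwann cell and glia genes were higher in 8 of 13 (median 0.38, adjusted p 0.531, 6 passed adjusted over the list alone), and members went both ways. The neural crest and otic transcription factor gene Sox10 had 37.7 and 15.5 against 108 and 100 FPKM, and S100b had 178 FPKM in vestibular 2 and 14.2, 4.32 and 2.36 in vestibular 1, cochlear 1 and cochlear 2. Melanocyte and intermediate cell genes were higher in 8 of 11 (median 1.23, adjusted p 0.396, none passed adjusted over the list alone and 1 had an unadjusted p under 0.05 in limma). The pigment enzyme gene Dct was listed at 0.561 FPKM in vestibular 1, 166 in vestibular 2 and 0 in both cochlear libraries. The median of the melanocyte list was 3.08 on the log2 scale in vestibular 2, and 0.715, 0.822 and 0.905 in vestibular 1, cochlear 1 and cochlear 2. Its direction thus rested on vestibular 2. Of 20 skeletal muscle genes 2 were kept, Tnnt1 and Tnnc1, and no value exceeded 4.01 FPKM. Of 10 red blood cell genes 7 were in the files and none was kept, the highest being Alas2 at 0.261 FPKM in cochlear 2.

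Otic patterning genes went both ways. Of the genes that pattern the dorsal, vestibular part of the ear, 7 of 10 were higher in vestibular cultures (median 0.44, camera adjusted p 0.646, 1 passed adjusted over the list alone). Bmp4 had 28.4 and 56.3 FPKM in the vestibular and 19.6 and 14.7 in the cochlear libraries, whereas Lmx1a had 4.28 and 0.842 against 52.1 and 47.0. Of the genes that pattern the ventral, cochlear part, 8 of 11 were higher in cochlear cultures (median -0.42, adjusted p 0.133; 0.0238 without vestibular 1), and 3 passed adjusted over the list alone. Gata3, a transcription factor gene needed for cochlear development, had a mean of 3.62 FPKM against 45.4, and Eya1 12.5 and 19.5 against 40.0 and 38.8. Of 28 HOX genes 1 was kept, Hoxa2, at 5.15 and 2.04 against 1.18 and 2.19 FPKM. HOX genes above 0 numbered 17 in vestibular 1, 8 in vestibular 2, 6 in cochlear 1 and 8 in cochlear 2.

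Signalling lists did not pass camera. WNT genes were split 11 of 22 (median 0.03, adjusted p 0.848) with 5 past adjusted over the list alone, 4 of them higher in vestibular cultures. The secreted WNT inhibitor genes Sfrp4, Dkk3 and Sfrp2 had 767 and 722 against 195 and 264 FPKM, 248 and 211 against 54.6 and 32.7, and 98.6 and 151 against 31.5 and 27.3. BMP and TGF-beta target genes were higher in cochlear cultures in 13 of 22 (median -0.05, adjusted p 0.585, 3 past adjusted over the list alone). Id3 went the other way, at 238 and 301 against 190 and 166 FPKM. FGF genes were higher in cochlear cultures in 13 of 19 (median -0.30, adjusted p 0.133, 2 past adjusted over the list alone), with the growth factor gene Fgf1 at a mean of 9.05 against 50.9 FPKM. NOTCH genes were higher in vestibular cultures in 9 of 14 (median 0.39, adjusted p 0.552, 2 past adjusted over the list alone), with Hes1 at 20.6 and 17.1 against 12.8 and 11.5. IGF and insulin genes were higher in cochlear cultures in 8 of 14 (median -0.18, mean 0.20, adjusted p 0.827). None of them passed adjusted over the list alone and 5 had an unadjusted p under 0.05 in limma. The binding protein gene Igfbp2 went the other way from most members, at 1751 and 1742 against 425 and 677 FPKM. Retinoid genes were higher in vestibular cultures in 7 of 13 (median 0.19, adjusted p 0.699, 2 past adjusted over the list alone). Aldh1a1 went the other way, at 134 and 80.8 against 198 and 212 FPKM.

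Genes of glycolysis and the hypoxia response were lower in vestibular cultures in 23 of 23 members (median log2 difference -0.74, camera adjusted p 1.76e-09, and adjusted p 0.912 with an estimated correlation). The glycolytic enzyme genes Aldoa, Pgk1 and Ldha had 1139 and 938 against 1866 and 1548 FPKM, 475 and 286 against 1012 and 885, and 602 and 524 against 980 and 856. Pkm, the pyruvate kinase gene, had 837 and 684 against 1240 and 1026. In this list 16 members passed adjusted over the list alone and 17 had an unadjusted p under 0.05, all lower in vestibular cultures. The list passed camera without any one library (adjusted p up to 1.03e-06, without cochlear 1). The epithelial list moved in the same direction between the groups.

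Ribosomal protein genes were lower in vestibular cultures in 33 of 36 members by a small amount (median log2 difference -0.26, camera adjusted p 0.00236, and adjusted p 0.912 with an estimated correlation). The call was lost without vestibular 2 (adjusted p 0.255, median -0.11) and without cochlear 1 (0.0636, median -0.25), and the median was -0.41 without vestibular 1. No member passed adjusted over the list alone and 2 had an unadjusted p under 0.05 in limma. Interferon response genes were higher in vestibular cultures in 22 of 27 (median 0.31, camera adjusted p 0.0154, and adjusted p 0.912 with an estimated correlation), with 1 past adjusted over the list alone. The interferon call was lost without vestibular 1 (adjusted p 0.0615) and without cochlear 2 (0.0988), the library low in macrophage genes, where the median was 0.16. Over all alternatives the interferon median ran from 0.13 to 0.52. Among its members with the highest values, the interferon-induced membrane protein gene Bst2 had 178 and 170 against 171 and 136 FPKM, and Irf9 a mean of 19.8 against 17.6. Members with larger differences, chosen after their values were seen, were Isg15 (22.2 and 21.7 against 11.3 and 10.2 FPKM) and Ifit3 (16.6 and 19.1 against 5.98 and 3.38), and 7 of the 27 had an unadjusted p under 0.05, 6 of them higher in vestibular cultures.

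**Figure D3:**
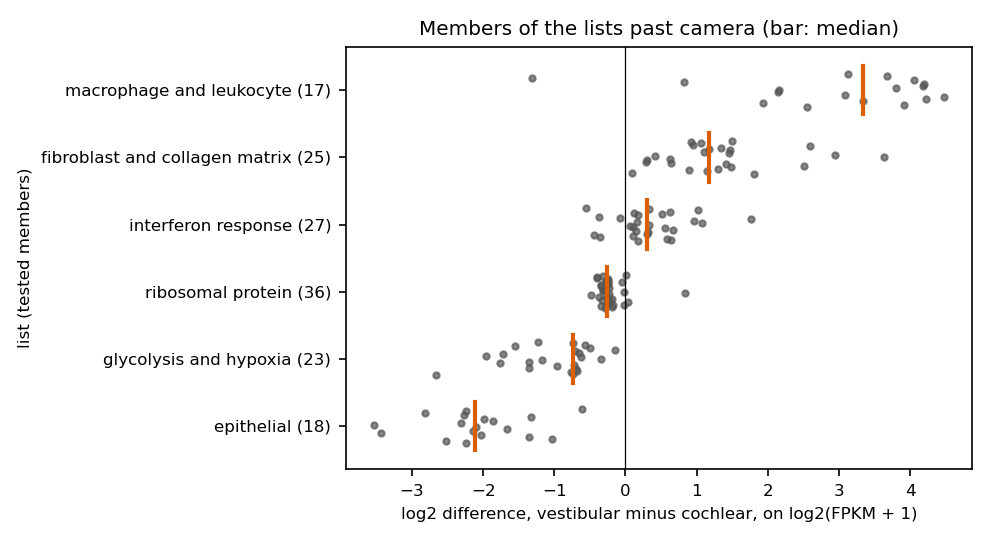
Log2 difference of each tested member, vestibular minus cochlear on the log2(FPKM + 1) scale, for the 6 lists past camera, with one grey point per gene (spread vertically for view) and an orange bar at the list median. All 23 glycolysis and hypoxia genes and all 18 epithelial genes lie below 0, and all 25 fibroblast and collagen matrix genes lie above 0.

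Stress and inflammation lists did not pass camera. Inflammatory cytokine and acute phase genes were higher in vestibular cultures in 13 of 19 (median 0.56, adjusted p 0.184; 0.00144 without vestibular 2), with 2 past adjusted over the list alone. Lcn2, the siderophore-binding lipocalin gene, had 3946 and 23.9 FPKM in vestibular libraries 1 and 2, and 453 and 1342 in cochlear libraries 1 and 2. Immediate early genes were higher in cochlear cultures in 16 of 19 (median -0.25, adjusted p 0.334; 0.00325 without vestibular 1), with Egr1 at 101 and 8.28 against 65.2 and 18.1 FPKM. Heat shock and chaperone genes were split 8 higher and 10 lower of 18 (median -0.01, adjusted p 0.827), although the small heat shock protein gene Cryab had 303 and 167 against 748 and 1069 FPKM. Oxidative stress genes under NRF2 were higher in vestibular cultures in 15 of 21 (median 0.25, adjusted p 0.167, 1 past adjusted over the list alone), with the ferritin genes Ftl1 and Fth1 lowest in cochlear 2 (2128 and 1063 FPKM). Genes of metal transport and the metallothioneins were higher in vestibular cultures in 8 of 14 (median 0.17, mean -0.06, adjusted p 0.848, 2 past adjusted over the list alone). Mt1 went the other way, at 209 and 86.6 against 328 and 216 FPKM. In the immediate early and heat shock lists none passed adjusted over the list alone, with 1 and 2 members at an unadjusted p under 0.05 in limma.

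The remaining lists did not pass camera either. Cell cycle genes were higher in vestibular cultures in 20 of 28 (median 0.14, adjusted p 0.296). The replication clamp gene Pcna overlapped between groups, at a mean of 53.2 against 57.3 FPKM. Cholesterol synthesis genes were higher in cochlear cultures in 14 of 20 (median -0.13, adjusted p 0.205; 0.00104 without vestibular 2), with Msmo1 at 25.3 and 24.8 against 34.0 and 36.3 FPKM. Adipogenic genes were higher in vestibular cultures in 8 of 13 (median 0.35, adjusted p 0.827), with the lipoprotein gene Apoe at 7891 and 7802 against 5212 and 1581 FPKM. In these 3 lists none passed adjusted over the list alone, with 0, 1 and 1 members at an unadjusted p under 0.05 in limma. Connexin and ion channel genes were higher in cochlear cultures in 10 of 19 (median -0.08, adjusted p 0.651, 2 past adjusted over the list alone), and the water channel gene Aqp5 had 1.72 and 0.771 against 35.5 and 73.4 FPKM. Sex-linked genes did not pass camera as a list (median 0.08, mean -0.23, adjusted p 0.646, none of 5 past adjusted over the list alone and 1 at an unadjusted p under 0.05 in limma). The list holds X-linked and Y-linked genes, which can move in opposite directions, so this does not exclude a difference in sex. The Y-linked gene Eif2s3y had 25.6 and 18.1 FPKM in the vestibular and 22.6 and 22.2 in the cochlear libraries, while Xist had 0.0118 FPKM in vestibular 1 and at least 18.3 in each other library.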

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

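The adjusted p below 0.10 and the removal of short noncoding RNA genes were chosen after seeing the data, and the other alternatives before. The 4 genes that differed, all lower in vestibular cultures, remained 4 with a pseudocount of 5, upper quartile scaling, no variance trend, robust variance, a log2 minimum of 1 and one row per symbol (no symbol had a second row), with 4 shared each time. The count was 3 at a mean FPKM of 5, with quantile normalization and without short noncoding RNA genes, and 2 with no filter (18257 genes tested), both higher in cochlear cultures. With a pseudocount of 0.1 there were 4, 1 of them higher in vestibular cultures (Mir678) and 3 higher in cochlear cultures. TPM scaling gave 5, 1 of them higher in vestibular cultures (Mir678), against 0 as reported. An adjusted p below 0.10 gave 135 genes, 22 higher in vestibular and 113 higher in cochlear cultures, and 15 listed genes, where the threshold of 0.05 gave 0. Leaving out any one library gave 0 genes (lowest and highest 0), with fewer samples to estimate the spread. With the replicate number as a block the count was 0, both overall and for genes higher in cochlear cultures. Over all genes, the deviations of same-numbered samples had a correlation of 0.0432 over 2 pairs, but the second principal component separated the libraries by number. A shared batch can thus be neither shown nor excluded. The labels name no pairs, so the numbers are not read as pairs. This block leaves the log2 differences as they were, so a call lost under it is not a weaker effect. Of the lists, 6 passed as reported, 10 with TPM scaling, and from 4 to 10 with a library left out (without cochlear 2 and without vestibular 1). None passed with an estimated correlation (0), while fry, which does not compare a list with other genes, gave 1 with its directional and 28 with its mixed test. The fibroblast, epithelial and glycolysis lists passed in 13 of 15 alternatives, failing with the estimated correlation and fry, the interferon and ribosomal lists in 11, and the macrophage list in 7. The cause of the gains and losses was not tested except that leaving out a library leaves fewer samples. Over single lists 539 outcomes stayed on their side of the threshold, 21 gained and 22 lost, and over named genes 3272 stayed, 25 gained and 25 lost. Only the 4 called genes and the 6 called lists could lose, so these totals do not measure how stable the calls were. Most named genes stayed because they never passed, and 23 of their 25 gains came with the adjusted p below 0.10. No call changed direction. For the similarity of libraries, the mean within-group minus between-group correlation was 0.0484 and lay between 0.0181 (without vestibular 2) and 0.0915 (without cochlear 1). Fragment counts are unknown, so what depth limits for single low genes could not be computed.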

Other observations

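The tests of lower depth, missing macrophages, the parts of the ear, scaling, epithelial share, the Snora44 fragments and the splits of the samples were chosen only after the result was seen, as were the genes named in the next paragraph and the limits behind the genes of single libraries.

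At the looser adjusted p of 0.10, 113 genes were higher in cochlear and 22 in vestibular cultures, and those named here were chosen after their values were seen. Slc26a4, which encodes pendrin, an anion exchanger of the endolymph-lining epithelium mutated in inherited deafness, had 60.5 and 46.3 FPKM in the cochlear and 1.93 and 0.884 in the vestibular libraries. The tight junction gene Cldn14 had 11.6 and 9.31 FPKM in the cochlear libraries and was listed at 0 and 0.0890 in the vestibular libraries. The sodium-proton exchanger gene Slc9a4 had 38.4 and 31.5 against 1.22 and 0.182, and the potassium channel gene Kcnk5 had 8.22 and 8.63 against 1.03 and 0.477. The growth factor genes Bmp6 and Bmp7 had 35.1 and 53.0 against 3.09 and 3.04 FPKM, and 26.8 and 26.7 against 4.87 and 3.62. A pair of abundant ubiquitin ligase component genes stood with them: Fbxo2 at 855 and 1275 against 114 and 98.0 FPKM, and Skp1a at 1564 and 1672 against 271 and 293. Among the 22 genes higher in vestibular cultures were the basement membrane gene Nid2 (104 and 70.5 against 15.2 and 12.1 FPKM), the cartilage matrix gene Matn4 (47.4 and 26.6 against 2.67 and 2.34) and the synaptotagmin gene Syt4 (12.7 and 11.5 against at most 0.879).

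The libraries of a group differed in cell type genes. With short noncoding RNA genes left out, 12 genes stood at 20 FPKM or more in vestibular 2 and at least 8-fold above the other 3 libraries on the FPKM + 1 scale. They include melanocyte genes (Dct, Mlana), cartilage genes (Col9a3, Col11a2) and Otos, a gene of spiral ligament fibrocytes, at 382 FPKM against 4.43, 14.1 and 1.45 in vestibular 1, cochlear 1 and cochlear 2. A further 13 genes stood at least 8-fold below the other 3 in vestibular 2, 5 of them epithelial markers. In vestibular 1, 5 genes stood above and 1 below: Ttr, the transthyretin gene, had 77.9 FPKM and at most 3.03 in the others, and Epyc, a proteoglycan gene, had 1.11 FPKM against 25.2 in vestibular 2, 391 in cochlear 1 and 747 in cochlear 2. In cochlear 1 and cochlear 2, 1 gene each stood above, and 66 stood below in cochlear 2 against 0 in cochlear 1.

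Of those 66 genes low in cochlear library 2, 14 are on the macrophage and leukocyte list, and of its 17 genes with at least 10 FPKM in cochlear 1, 15 (88.2%) stood below 5 percent of that value in cochlear 2, with the exceptions Cd74, at 270 percent, and Cd14, at 12.9 percent. Lower depth is argued against, since 1 fragment in cochlear 2 was worth at most 0.977 times its worth in another library. A wrong label is too: over 151 genes separating both vestibular libraries from cochlear 1 by a log2 of 2 or more, cochlear 2 lay nearer cochlear 1 in 128 (84.8%). A difference between the parts of the ear is argued against as the whole cause, because the vestibular mean minus cochlear 1 had a median log2 of 0.05 over the list (quartiles -0.11 and 0.25), while cochlear 1 exceeded cochlear 2 by 6.44. A loss of macrophages from that culture stays open, since the listed genes that would test it are those that show the pattern. Among the 66, genes outside the macrophage list, chosen after their values were seen, include Ctss, Trem2 and Spi1, and also the collagen gene Col1a1. In cochlear 1 they had 417, 130, 38.9 and 84.2 FPKM, and in cochlear 2 they were listed at 1.02, 0.306, 0 and 8.86. They too were picked by their low value in cochlear 2, so they do not decide it.

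The glycolysis and hypoxia genes lower in vestibular cultures stood apart from other genes by camera at the preset correlation. This call was lost with an estimated correlation (camera adjusted p 0.912, estimated correlation 0.398). The list passed camera at the preset correlation under upper quartile, quantile and TPM scaling (adjusted p 5.43e-10, 2.13e-10 and 5.87e-10). On the log2(FPKM + 1) scale a factor per library moves abundant genes alike and low genes less. A test against other genes responds little to such a factor, so these passes do not decide about scaling. A trend on transcript length and GC content shared by all genes is argued against: over 12733 genes it held 0.294 percent of the variance of the log2 difference, and removing it left a median of -0.761 (23 of 23 members with a value, quartiles -1.39 and -0.65). Whether the list also fell in absolute terms stays open: its median was -0.74 and that of all genes tested 0.01, but the scaling of the deposited values is not given and may have set the latter. Cell makeup stays open too, by the median over genes of the log2 difference between 2 libraries. Vestibular 1 minus vestibular 2 was 2.15 for the epithelial and 0.323 for the glycolysis list. Cochlear 2 minus cochlear 1 was 0.38 for the epithelial list but -0.19 for the glycolysis list. The epithelial share cannot be told apart from the groups with these 4 libraries, and a difference between the parts of the ear was not tested.

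Snora44 passed the threshold with 44.8 and 43.8 FPKM in the cochlear libraries. Their ratio, 1.0234, equals the ratio of what 1 fragment is worth in these libraries within 0.1 percent, which is consistent with the same number of fragments in both libraries. At a length of 129 nt that number may be small, and no biological explanation was tested. The 4 libraries split into 2 and 2 in only 3 ways, too few for a share under 0.05. In 2 of the 3 splits, the real one included, at least 4 genes passed: the real split gave 4, and the highest of the others gave 5. At an unadjusted p under 0.05 the real split gave 2398 genes and the other splits 218 and 142. In the other splits the difference between vestibular and cochlear libraries adds to the spread within groups. Their counts are thus no measure of chance.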
